A study of Homo sapiens with 6 samples.

How the data were processed

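Gene expression was measured on 1-colour microarrays in 6 samples of KM-H2, an established Hodgkin lymphoma cell line that the labels write as KMH2. Cells were sorted by flow cytometry into the side population (SP) and the remaining cells (non-SP). A side population is the set of cells that stay dim after incubation with a DNA-binding dye because membrane transporters pump the dye out. Each group held 3 samples, numbered 1 to 3 in the labels. Nothing in the labels says whether the 3 came from separate cultures or sorts, so the p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, cells were grown in RPMI medium with fetal bovine serum, total RNA was isolated with Trizol and treated with DNase, and the RNA was labelled with Cy3 using a kit for low RNA input.

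Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1 (10.7 in the submitters' processing notes) under a 1-colour gene expression protocol. Each deposited file held 45015 spots, of which 43376 carried 41000 different non-control probes. The deposited processed signal is a linear intensity per spot that Feature Extraction had corrected for background, per the file headers, with no scaling between arrays. The raw median spot and background intensities and the quality flags of each spot were also deposited by the authors. The deposited series table holds log2 values of 40424 of these probes and 89 control rows. Set against the scanner values of the same array, its columns had a slope of 1 on log2 processed signal and differed from the scaled values used here by a median of at most 0.00241, so its scale is log2 and it is centred on the same percentile. Its column medians were -3.15, -3.29 and -3.28 for SP 1 to 3 and -3.27, -3.37 and -3.42 for non-SP 1 to 3.

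The main values were log2 of the processed signal minus the 75th percentile of each array over non-control probes. Spots of a probe were averaged, spots with an outlier flag and control spots were left out, and 58 probes with only such spots on an array were dropped. A probe was tested when it was well above background on all 3 arrays of at least 1 group, which held for 21637 probes. Of the 41000 probes, 26386 matched 1 gene symbol through their RefSeq accession (26386 of 27130 probes with an NM or NR accession), none matched several, and 14614 had no gene name here. The reference table was made for assembly GRCh38 and the grid for hg19, so it served for names only and no coordinates are given. Where a gene had several tested probes, its value came from the probe with the highest mean signal. Other probes of opposite sign are given in the text, and those that differed only in size are given for some genes.

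SP was compared with non-SP by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups, no block), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Differences are SP minus non-SP on the log2 scale. A probe not well above background on any array of a group has only a bound there. Its fold is given as at least the brighter group's mean over the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Gene lists, 49 of them, were written before the data were examined. The 48 with at least 5 tested genes were tested with camera (preset correlation 0.01) on 1 probe per gene, and the list of mitochondrially encoded transcripts had no tested gene. Camera with an estimated correlation and fry were run beside it.

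Named genes followed a rule written before the data were examined. It took the 10 largest differences in each direction among probes past the threshold whose groups did not overlap and that were well above background on all arrays of the higher group. To these it added up to 4 genes past the threshold from each list, the 3 tested members of smallest p from each of 5 lists (antioxidant enzymes, NRF2 targets, enzymes that form oxidants, oxidative phosphorylation and ABC transporters), and a fixed set of redox, transporter and lymphoma genes. TXNIP was in that set, and its probes did not pass the background filter. A gene that the rule also took is not reported here.

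The file headers place SP and non-SP samples of the same number on the same slide, 3 slides in all, with SP always at position 3 and non-SP at position 4. Position and group therefore cannot be told apart. Slide and group can, and the slide was fitted as a block beside the main fit. That fit is also the fit with the replicate number as a block. Deviations from the group means correlated at 0.16, -0.13 and 0.30 between samples of the same number, so these values did not show the numbers to pair the samples. No pair of arrays held the same value for any tested probe.

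Alternatives were normexp background correction on the median spot signal (the mean spot signal was not used here), quantile normalization, scaling to the median, no scaling, other background filters, trend and robust estimation, array weights, the deposited series table, and leaving out each array. The arrays with the probe and list tests were also simulated with independent probes, using the real means and spreads and 200 changed probes among 21637. For SP against non-SP, 95% of 4-fold and 28% of 2-fold changes were called with the right sign, with 8 unchanged probes among 131 called. In the list test on 10997 genes, 4 of 4 shifted lists were called and 0 unshifted ones. The simulated shift was larger than the median, without sign, of every list that passed here except G2 and M phase. Independent genes also cannot show how often lists of correlated genes are called in error. The number of arrays limits the precision.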

Results

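The comparison was made to find why reactive oxygen species are lower in side population cells than in the other cells of Hodgkin lymphoma lines. Expression was compared between 3 SP and 3 non-SP samples of KM-H2 cells. Between 52.0% and 58.8% of the 41000 probes were well above background on an array, with 22513, 24100 and 22752 such probes in SP 1 to 3 and 22170, 21335 and 22488 in non-SP 1 to 3. The 75th percentile of the processed signal was 188, 352 and 161 in SP 1 to 3 and 239, 227 and 258 in non-SP 1 to 3. Array SP 2 was the brightest. Over the tested probes it correlated with the non-SP arrays at 0.978 to 0.983 and with SP 1 and SP 3 at 0.981 and 0.970, while SP 1 and SP 3 correlated at 0.986. SP 1 and SP 3 correlated with the non-SP arrays at 0.956 to 0.978.

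SP and non-SP cells differed at 434 of 21637 tested probes (2.01%), of which 363 were higher and 71 lower in SP (limma, adjusted p below 0.05). The difference was at least 2-fold at 387 of them. By the brightest probe of each gene, 154 genes were higher and 29 lower among 10997 tested. The largest rise was in NPAS3, a transcription factor known from neurons, at 5.50 ± 0.11 in SP and -0.07 ± 0.24 in non-SP (log2 relative to the 75th percentile, mean ± SD, n = 3), which is 47.3-fold (log2 difference 5.57 ± 0.19 SE, limma adjusted p = 6.4e-05). Among named genes well above background in both groups, the largest fall was in PIF1, a DNA helicase, by 1.81 on the log2 scale. The other 2 tested probes of PIF1 were at -2.27 and -0.33, and 1 of them passed. All 434 probes had groups that did not overlap and changed the same way on all 3 slides. The probes were called on these same arrays, and groups that do not overlap must differ the same way on every slide. Neither is therefore a separate check. Of all tested probes, 21.8% had groups that did not overlap, against 10% expected by chance.

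The other genes with the largest rises included several known from other tissues. The homeobox gene IRX3 was 39.5-fold higher (5.30 ± 0.44 SE) and was well above background on 2 of 3 non-SP arrays. The sulfate and oxalate transporter SLC26A1 was 29.9-fold higher (4.90 ± 0.48 SE), and GPR132, a lysolipid- and proton-sensing receptor of leukocytes, was 18.5-fold higher, with 2 of 3 non-SP arrays well above background. SCGB3A2, a secretoglobin of the airway epithelium, was not well above background on any non-SP array and was at least 5.06-fold higher. The same held for CLDN14, a tight junction protein (at least 2.15-fold), the pseudogene ZNF137P (at least 1.80-fold) and the procollagen-processing protease ADAMTS14 (at least 1.58-fold). ATCAY rose by 2.57 and was well above background on 1 of 3 non-SP arrays, and EBLN2, derived from an ancient viral sequence, rose by 2.43. Normexp background correction, whose offset of 50 compresses dim signals by construction, gave smaller differences for the genes that were dim in non-SP. The log2 difference was then 3.65 for IRX3 and 2.35 for GPR132, which kept their calls, and 0.95 for SCGB3A2, 0.60 for CLDN14, 0.57 for ATCAY, 0.49 for ADAMTS14 and 0.47 for ZNF137P, which did not pass (limma adjusted p from 0.0542 to 0.330). With quantile normalization beside it SCGB3A2 passed (0.85, adjusted p = 0.0481). Of the 363 higher probes, 100 were not well above background on any non-SP array, and 156 had no gene name here. Of the 71 lower probes, 4 were not well above background on any SP array, and 37 had no gene name here. Among tested probes, 2.63% of those without a gene name were called higher, against 1.32% of those with one.

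**Figure D1:**
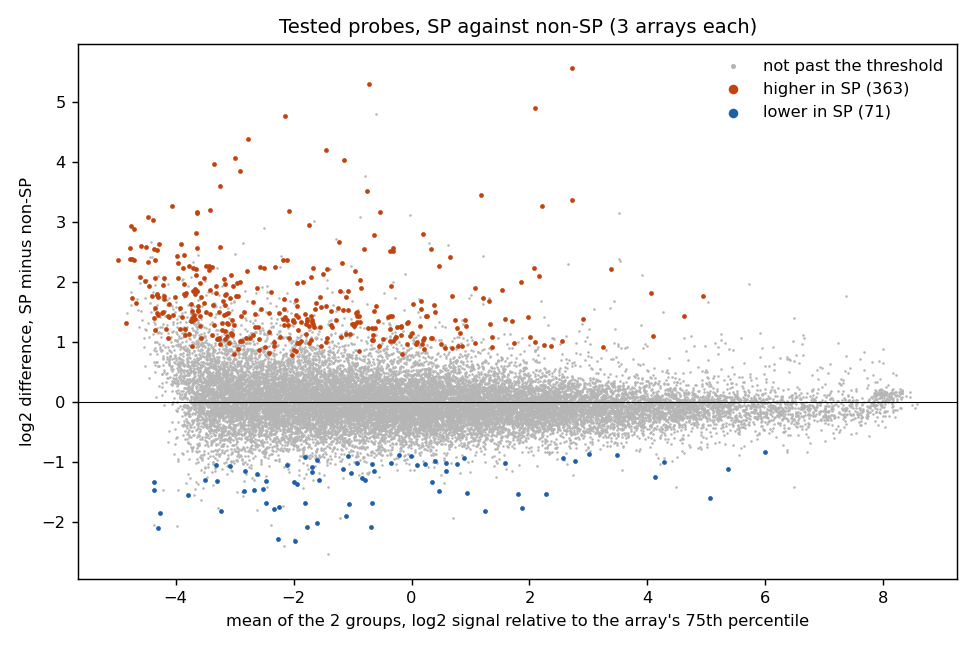
Each point is a tested probe, by its mean log2 signal over both groups (relative to the array's 75th percentile) and its log2 difference, SP minus non-SP, with probes past the threshold in red (363 higher) and blue (71 lower). The higher probes reach 5.57 (NPAS3) and many lie among the dim probes on the left.

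Genes of cell division were among the largest falls. TOP2A, the topoisomerase that untangles chromosomes before division, was at 0.99 ± 0.34 in SP and 2.76 ± 0.13 in non-SP (SD, n = 3; difference -1.77, adjusted p = 0.0135 by limma), and CDK1, the kinase that drives entry into mitosis, was at 1.52 ± 0.20 and 3.04 ± 0.04 (difference -1.53, adjusted p = 0.0107). Among the 34 tested genes of the G2 and M phase list, 33 had negative differences, 4 fell, and 30 did not pass the test over all probes. Adjusted over the list alone, 21 fell. The other members past the threshold were the spindle protein NUSAP1 (-1.03) and the kinetochore motor CENPE (-0.93), which did not pass with the slide as a block (adjusted p of 0.0892 and 0.0738). The list's median difference was -0.61 (camera adjusted p = 3.0e-16, and adjusted p = 0.621 with an estimated correlation). Its median was -0.58, -0.63 and -0.61 on slides 1 to 3. Cytokinesis genes shifted the same way, with a median of -0.39 over 19 genes (camera adjusted p = 0.00141, and adjusted p = 0.756 with an estimated correlation) and of -0.36, -0.48 and -0.40 on slides 1 to 3. CDCA8, a subunit of the chromosomal passenger complex, was the only member past the threshold over all probes (-0.99, adjusted p = 0.0686 with the slide as a block), while 5 fell and 1 rose adjusted over the list alone. The S phase list did not pass, with a median of -0.01 over 39 genes (camera adjusted p = 0.906) and no member past the threshold.

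The remaining genes with the largest falls were of several kinds. UBA7, which activates the ubiquitin-like protein ISG15, was not well above background on any SP array and was at least 2.13-fold lower. With normexp background correction its difference was -0.26 and did not pass (adjusted p = 0.684). SNAI1, a repressor of epithelial genes, fell by 1.51 and NRN1L fell by 1.68. AGER, the receptor for advanced glycation end products, fell by 1.33, as did ZNF296. DNM3, a dynamin, fell by 1.47, and the cytoskeletal gene SEPTIN10 fell by 1.35. With normexp background correction AGER kept its call (-1.10), while ZNF296 (-0.49), DNM3 (-0.35) and SEPTIN10 (-0.56) did not pass (adjusted p of 0.283, 0.481 and 0.137). With quantile normalization beside it SEPTIN10 passed (-0.67, adjusted p = 0.0481).

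Among genes that handle oxidants, few passed. SLC7A11, the cystine carrier that feeds glutathione synthesis, rose 2.94-fold (1.56 ± 0.28 SE, limma adjusted p = 0.0396), and was near the threshold with normexp background correction (0.88, adjusted p = 0.0568, and 0.84, adjusted p = 0.0493, with quantile normalization beside it). HMOX1, which degrades heme, had a mean of 4.97 ± 1.06 in SP and 2.85 ± 0.80 in non-SP (SD, n = 3). That difference of 2.12 did not pass over all probes (limma adjusted p = 0.125), and with the slide as a block it did (adjusted p = 0.0382), with differences of 2.40, 1.43 and 2.51 on slides 1 to 3. Of 21 NRF2 targets tested, 1 rose, none fell and 16 had positive differences. SLC7A11 was also the only one past the threshold adjusted over the list alone. Their median difference was 0.32 (camera adjusted p = 0.00792, adjusted p = 0.946 with an estimated correlation and adjusted p = 0.477 by fry), and it was 0.06, 0.45 and 0.45 on slides 1 to 3 (adjusted p = 0.0024 with the slide as a block). The shift was not past the threshold without SP 2 (adjusted p = 0.101) or without SP 3 (adjusted p = 0.0608). NFE2L2, which encodes NRF2 itself, differed by 0.56 (adjusted p = 0.167).

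Antioxidant enzymes as a list did not pass by camera (24 genes, median -0.11, camera adjusted p = 0.498, and medians of -0.09, -0.16 and -0.08 on slides 1 to 3), and no member passed over all probes or adjusted over the list alone. The differences were -0.05 for the superoxide dismutase SOD1, 0.02 for SOD2, -0.22 for catalase (CAT), -0.10 for GPX1, -0.19 for GPX4 and 0.48 for thioredoxin (TXN), each with a limma adjusted p of at least 0.441. The members of smallest p were SOD3 (0.70), SRXN1 (0.65) and PRDX5 (-0.54), at adjusted p of 0.167, 0.171 and 0.206. With normexp background correction PRDX5 turned to 0.24. NQO1, another NRF2 target, differed by 0.34 (adjusted p = 0.628).

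The enzymes that form oxidants were tested for 9 genes, and their list did not pass (median -0.29, camera adjusted p = 0.840, and medians of -0.11, -0.16 and -0.20 on slides 1 to 3). CYBB, the catalytic subunit of the phagocyte oxidase, differed by -0.51 (adjusted p = 0.375). PTGS1 (1.12) and MAOA (at least 1.40-fold higher, not well above background on any non-SP array) did not pass over all probes (adjusted p of 0.116 and 0.118) and were the 2 higher genes adjusted over the list alone. Oxidative phosphorylation, the main source of mitochondrial oxidants, had a median of -0.07 over 76 genes (camera adjusted p = 0.202), with medians of -0.09, -0.28 and 0.16 on slides 1 to 3 and no gene past the threshold. The members of smallest p were CYCS (-0.69, adjusted p = 0.0856), SDHD (-1.06, adjusted p = 0.132) and ATP5F1C (-0.65, adjusted p = 0.287). This list passed without SP 3 (median -0.17, camera adjusted p = 0.00391) and with normexp background correction (median -0.15, adjusted p = 0.00347), but not with normexp and quantile normalization together (median -0.05, adjusted p = 0.484).

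Transporters that can pump out the dye were looked at because they define the gate. ABCG2 had a mean of 2.96 ± 0.22 in SP and 2.31 ± 0.16 in non-SP (SD, n = 3), a difference of 0.65 that did not pass (limma adjusted p = 0.149) and that was positive on all 3 slides (0.74, 0.37 and 0.84). ABCB1 differed by -0.11 (adjusted p = 0.866). It was dim, and its sign turned with normexp background correction scaled to the 75th percentile, with array weights and without some arrays. The list of 17 ABC transporters did not pass (median -0.12, camera adjusted p = 0.840, and medians of -0.19, -0.16 and -0.10 on slides 1 to 3), and ABCA7 (-0.51) and ABCC5 (0.37) also did not pass.

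**Figure D2:**
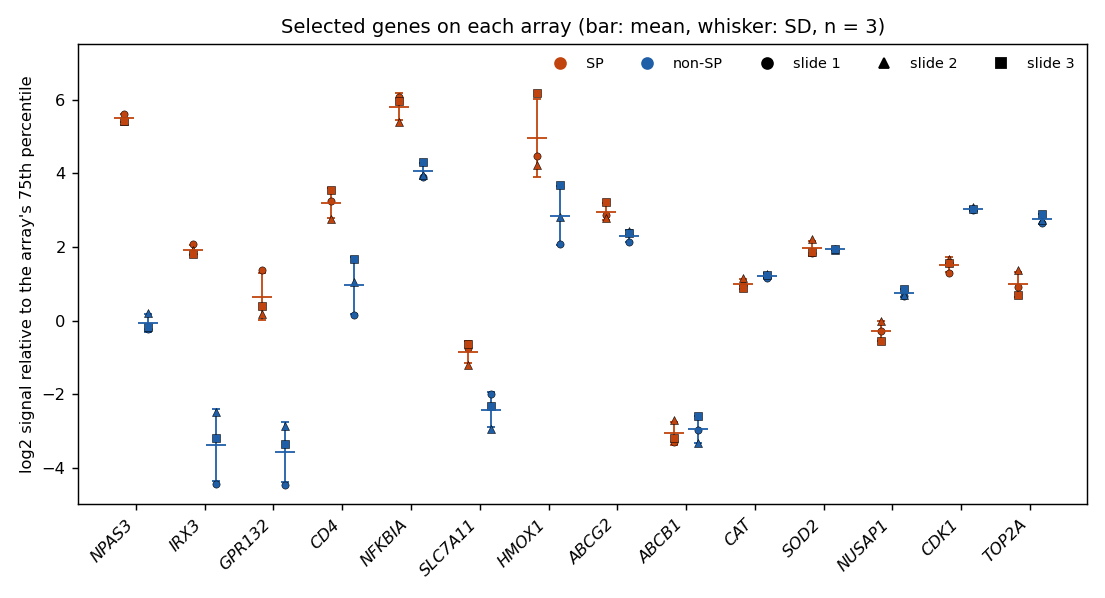
Points are the log2 signals of 14 selected genes on each array, relative to the array's 75th percentile, in SP (red) and non-SP (blue), with shapes for the 3 slides, bars for means and whiskers for the SD (n = 3). The groups of ABCB1 and SOD2 overlap, and those of the other genes lie apart, as did those of 21.8% of all tested probes. HMOX1, ABCG2 and CAT lie apart without passing the test. The means of HMOX1 are 4.97 and 2.85 with the widest spread in SP, and those of SOD2 are 1.97 and 1.94.

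Single genes of signalling pathways also rose. NFKBIA, the inhibitor of NF-kB that NF-kB itself induces, rose 3.40-fold (5.82 ± 0.37 in SP, 4.05 ± 0.22 in non-SP, SD, n = 3, limma adjusted p = 0.0181), and the cytokine TNF rose 2.16-fold (adjusted p = 0.0831 with the slide as a block). The NF-kB target list as a whole did not pass (27 genes, camera adjusted p = 0.360, median -0.07 with a test in the positive direction). Adjusted over the list alone 6 members rose and 1 fell, and by fry in either direction its adjusted p was 0.0025. SOCS1, which restrains cytokine signalling, rose by 1.42, and KLF6, a rapidly induced transcription factor, by 0.96. With the slide as a block neither passed (adjusted p of 0.0805 and 0.0717). The other probes of SOCS1 and KLF6, at 1.15 and 0.49, did not pass in the main fit. Immediate early genes, which cells switch on within minutes of a stimulus, had a median of 0.37 over 22 genes (camera adjusted p = 0.00173, and adjusted p = 0.756 with an estimated correlation), with KLF6 past the threshold and 10 genes higher adjusted over the list alone. Their median was 0.45, 0.16 and 0.44 on slides 1 to 3. MHC class I presentation genes had negative differences in 16 of 16 (median -0.30, camera adjusted p = 0.00173, and adjusted p = 0.672 with an estimated correlation), and no member passed over all probes or adjusted over the list alone. Their median was -0.44, -0.20 and -0.30 on the 3 slides. Hypoxia response genes had a median of 0.19 over 21 genes (camera adjusted p = 0.0334, and adjusted p = 0.788 with an estimated correlation), with no member past the threshold and medians of 0.30, 0.03 and 0.15 on the 3 slides. That call was lost without non-SP 1 (adjusted p = 0.0567) or non-SP 2 (adjusted p = 0.127), with no scaling (adjusted p = 0.151) and with no filter (adjusted p = 0.279).

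**Figure D3:**
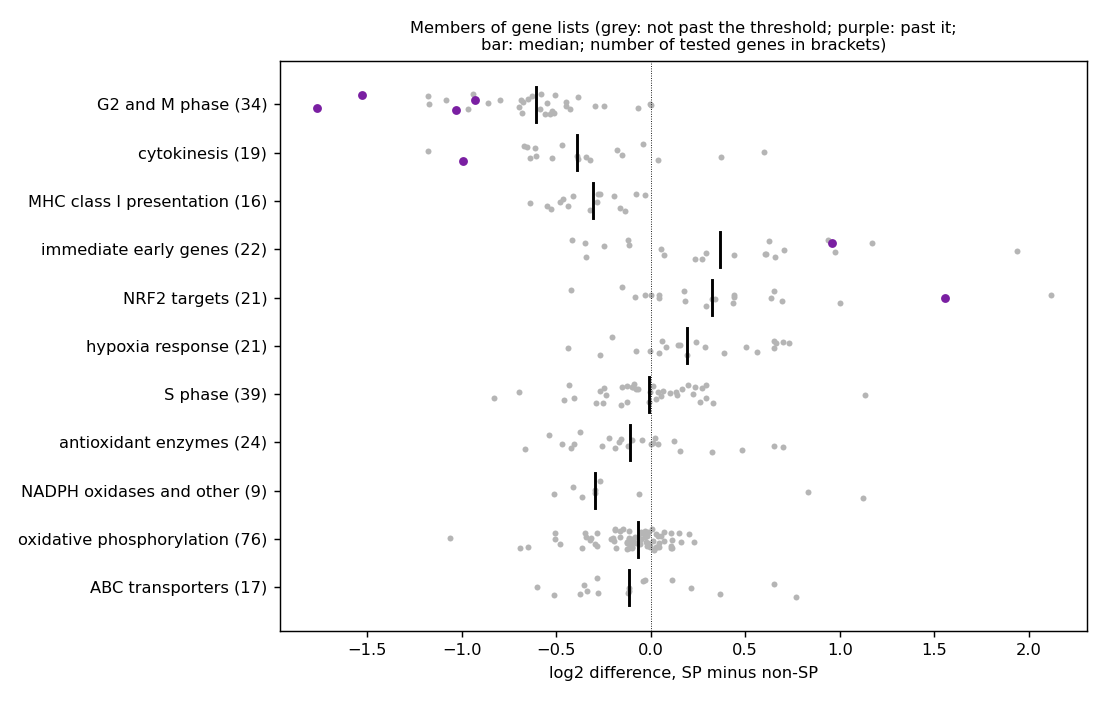
Each point is a tested gene of a list, by its log2 difference, SP minus non-SP, with genes past the threshold in purple and a bar at the list's median. The G2 and M phase list (median -0.61) lies almost wholly below 0, and the antioxidant list (median -0.11) spreads on both sides of 0.

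Members of other lists past the threshold were spread over many functions. CD4, a lymphocyte and monocyte surface receptor, rose by 2.24. The p53-induced phosphatase PPM1D rose by 1.21, the Notch effector HES4 by 1.31, BACH1, a repressor of HMOX1, by 1.12, and the autophagy gene ATG16L1 by 1.00. The nuclear RNA KCNQ1OT1 fell by 0.88 on its brightest probe, and its other probe was at 0.18. TNFRSF8, which encodes the Hodgkin marker CD30, differed by 0.49 (adjusted p = 0.362), MYC by 0.70 (adjusted p = 0.216) and FOXO3 by 0.41 (adjusted p = 0.501). The lists for Hodgkin and Reed-Sternberg cells, B lineage, T and NK cells, myeloid, erythroid and stromal cells did not pass (camera adjusted p from 0.149 for myeloid genes to 0.965 for erythroid and platelet genes). In all, 6 of 48 lists passed, 3 in each direction. With an estimated correlation 0 passed. That form of camera takes its degrees of freedom from the 6 arrays, not from the number of genes, and has little power here. The estimated correlation of the 6 lists ran from 0.031 (MHC class I presentation) to 0.343 (NRF2 targets), and all lost their call. A call lost there thus does not show that correlation between genes made it. Directional fry, which tests whether a list moves 1 way on balance, passed 3 lists. They were G2 and M phase (adjusted p = 0.0272), MHC class I presentation (0.0446) and p53 targets (0.0464). Tested by fry for change in either direction, which does not compare a list with other genes, 25 lists passed, antioxidant enzymes among them (adjusted p = 0.0266). All 6 lists that camera passed also passed with the slide as a block (adjusted p from 1.0e-14 to 0.0273). Other splits of the 6 arrays into 3 and 3 gave up to 9 lists.

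The count of probes changed much when single arrays were left out, which also makes a group smaller. It was 54 without SP 1, 1112 without SP 2, 124 without SP 3, and 121, 170 and 205 without non-SP 1, 2 and 3, and it was 234 with the slide as a block, of which 202 were among the 434. It was 14 with no background filter and 716 with array weights. With the slide as a block 18 of the 35 named genes past the threshold did not pass, among them SCGB3A2, ATCAY, CLDN14, UBA7, SEPTIN10, ZNF296, HES4, ATG16L1, BACH1, KCNQ1OT1 and PPM1D, while NPAS3 (adjusted p = 0.00497), CDK1 (0.0357), SLC7A11 (0.0372) and TOP2A (0.0388) did.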

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

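The restriction to RefSeq probes, the settings that join the omission of an array with another choice, and the tests of the ZNF list were chosen after the data were seen. Causes were not tested, except that a filter or an omitted array changes what is tested. The deposited series table, quantile normalization, median scaling and trend with robust estimation kept every count within 1.5 times. Against 434 probes (363 higher, 71 lower, 387 of at least 2-fold), the counts were 189 (156, 33 and 112) with normexp, 233 (184 higher, 99 of at least 2-fold) with normexp and quantile normalization, and 91 (84, 7 and 91) with no scaling. They were 14 (14, 0 and 14) with no filter, where 3604 probes had an unadjusted p under 0.05, and 227 (179 higher, 202 of at least 2-fold) with all 6 arrays above background. Array weights, whose estimation stopped before convergence, gave 716 (588 and 128), and RefSeq probes alone 219 (189, 30 and 188). With the slide, and so the replicate number, as a block they were 234 (203, 31 and 234), and correlations of same-numbered samples did not all pass 0.1. Leaving out 1 array gave 54 to 1112 probes (46 to 718 higher, 8 to 394 lower, 54 to 889 of at least 2-fold). Without SP 2, quantile normalization gave 903 (380 lower, 725 of at least 2-fold) and normexp 2763 (1636 and 1127). The share of higher calls was 83.6%, and without SP 2 it was 64.6%. Median scaling and no scaling moved the median of all probes from -0.02 to -0.13 and -0.15.

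Lists past the threshold numbered 0 with an estimated correlation and 3 with directional fry, and 6 to 8 with 1 array left out. The NRF2 median of 0.32 lost its call in both of those tests, and its range with 1 array left out was 0.15 to 0.54. Oxidative phosphorylation passed with normexp (-0.15, but not with quantile normalization beside it, -0.052) and without SP 3, with a range of -0.17 to 0.016. The test of ABC transporters turned sign with normexp (median -0.0066), with no filter (-0.039) and with the probe of smallest p (-0.11). G2 and M genes lost their call only with the estimated correlation, at medians from -0.74 to -0.55 over 22 settings. Among the 35 named genes past the threshold, none reversed. The block cost 18 of them the call, no filter 32, no scaling 24 and normexp 13, and omission of SP 1 28 and of SP 2 only 2. Reversals were among genes that did not pass: PRDX5 at 0.24 and 0.34 with the normexp settings, ABCB1 at 0.052 with normexp and 0.080 with array weights (omissions -0.30 to 0.074), SOD1 at 0.013 with array weights (-0.23 to 0.097), SOD2 at -0.0042 with normexp, -0.084 with median scaling and -0.10 with no scaling (-0.097 to 0.088), and GPX1 (-0.23 to 0.030). Dim signal limits the bounds given for SCGB3A2, ZNF137P, ADAMTS14, CLDN14 and UBA7.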

Other observations

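Tests of the zinc finger family and the cell cycle, and those that omit an array under quantile normalization, were chosen after the results were seen. Genes whose symbol begins with ZNF and a digit were called far more often than others. Of 265 tested ZNF genes, 47 were higher and 1 lower in SP (17.7% higher), against 0.997% higher and 28 lower among 10732 other genes. Their median difference was 0.47 against -0.04 for the others, and 216 of 265 were positive. Most encode DNA-binding proteins that repress transcription. The hypothesis tested was that they may be higher as a family beyond what their low brightness gives. Over 6 scalings and background corrections, their median lay above all of 10000 random lists matched on brightness (lowest percentile 100), from 0.25 to 0.47, and the highest random median in the main setting was 0.096. Random lists treat genes as independent, and camera with an estimated correlation gave p = 0.0051 (correlation 0.049), with no adjustment for the other lists. The family was picked because its members were called on these same arrays, so neither value is independent evidence. Leaving out any 1 array gave 0.45 to 0.52. Members share similar sequence, and cross-hybridisation between them was not examined.

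Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 434 probes and the highest of the others 0, and 1 split reached the real count. With 10 splits the share cannot go under 0.1, so they are too few for a share under 0.05. For gene lists, 3 of the 10 splits gave at least the 6 lists of the real one, and the highest other gave 9. That split set SP 2, SP 3 and non-SP 2 against the rest, and the one that gave 6 set SP 1, SP 3 and non-SP 1 against the rest. The G2 and M median of -0.61 in the real split compares with -0.28 at most in the others. Those splits divide the SP arrays unevenly, so a smaller shift the same way is built in. The list's camera adjusted p ran from 1.2e-05 to 0.411 in them and was under 0.05 in most.

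More probes were higher than lower in SP (83.6% of calls). Whether brightness-dependent scaling between arrays was the whole cause could not be decided. Before the test, a share of at least 75% with quantile normalization was set to speak against it and one of at most 60% for it. With all arrays it was 79.8% of 331 calls (exact binomial interval 75.02% to 84.0%, which treats probes as independent and so is too narrow), and 75.8% to 85.0% with any array but SP 2 omitted. With SP 2 omitted it was 57.9%, under the 60%. That omission raised the higher calls from 264 to 523 and the lower ones from 67 to 380, and in the main setting, with no such correction, from 363 to 718 and from 71 to 394 (64.6% higher), so most of that fall came with the array. How to weigh the spread around the share was settled after the values were seen. The interval that cleared 75% is too narrow, and the share without SP 2 was under 60%, so scaling was not excluded. Genomic DNA in the samples was not tested for, though the RNA was treated with DNase per the labels' protocols. A difference between SP and non-SP cells stays open.

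Array SP 2 lay nearer the non-SP arrays than the other SP arrays did. Under quantile normalization, omitting SP 2 still raised the count by 2.73 times, from 331 to 903, and omitting any other array lowered it. A difference in overall brightness, which quantile normalization evens out, is thus argued against as the whole cause. Effects of brighter labelling that differ between probes are not evened out and were not excluded. Saturated probes numbered 201 on SP 2 and 87 to 164 on the other arrays. Non-SP cells in the SP 2 sample may contribute. The share of non-SP RNA estimated from probes higher in SP 1 and SP 3 was 0.433 (0.324 to 0.506, 106 probes). From probes lower in them it was 0.703 (0.567 to 0.795, 237 probes). The intervals, which hold only the spread over probes, did not overlap, so no single share gives both values. Estimated in the same way, the shares for SP 1 and SP 3 ran from 0.015 to 0.112. The gap of 0.270 lay between the limits set beforehand. Non-SP cells thus cannot be told apart from a sample that truly differed. Its spike-in controls were lowest relative to the array's 75th percentile, at -0.05 against 1.02 to 1.71 on the other arrays. That percentile was itself highest on SP 2 (352), so the low value is not a sign separate from the array's brightness.

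G2 and M phase genes were lower in SP. A lower share of cycling cells would lower S phase genes too. Their median was -0.011 (95% bootstrap interval over genes -0.12 to 0.06), above -0.30, which is the G2 and M median divided by 2. That limit is an assumption, and the interval holds no spread between samples. By slide, the S phase median was 0.030, 0.045 and 0.0036, and the G2 and M median was -0.58, -0.63 and -0.61. The S phase median thus fell on no slide. The mean of the S phase list, centred per gene, was higher in SP on slides 1 and 2. On slide 3 it was lower, at -0.038 in SP 3 and 0.121 in non-SP 3, against -0.305 and 0.405 for the G2 and M list. By the medians this argues against fewer cycling cells as the whole cause, but the test was set after both lists had been seen. A gate on dye brightness could favour cells of low DNA content, since the dye binds DNA and cells in G2 and M hold more of it. The G2 and M median lay -0.60 from the S phase median (interval -0.74 to -0.44), as this needs, but the gate defines the groups and the arrays hold no DNA content, so it cannot be told apart from a difference in expression of these genes.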
